A study of Caenorhabditis elegans with 4 samples.

How the data were processed

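Whole young adult Caenorhabditis elegans hermaphrodites of a pdf-1 knockout strain (LSC0027 in the labels) and of the wild-type strain N2 were compared on 4 two-colour Agilent oligonucleotide arrays. Per the labels, each RNA came from a biologically independent sample of about 12000 worms, was purified with a Qiagen kit, and 1 µg of it was mixed with 10 viral spike-in transcripts, amplified and labelled with Cy3 or Cy5. Each array carried 1 knockout RNA and 1 wild-type RNA. The arrays are named here by the replicate numbers in the labels, 1, 2, 4 and 5. The knockout RNA was in Cy3 on replicates 1 and 4 and in Cy5 on replicates 2 and 5. Per the file headers, all 4 arrays lay on 1 slide and share 1 scan time, so neither could be tested as a batch.

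Per the file headers and the submitters' processing notes, the deposited scanner values were read with Agilent Feature Extraction 9.5.3.1. The deposited intensity values used here were the mean signal of each spot and the median of its local background in both colours, neither of them normalized, and for 1 alternative the processed signals, which the scanner software had background-subtracted and dye-normalized per the file headers. The deposited log10 ratio of red over green was read only to settle direction. The authors' value table of the series holds log2 ratios. On each array 100% of the 43553 probes with a single spot agreed within 0.001 with log2 of the processed signal ratio turned to knockout over wild type, which settled its scale and direction. The medians of its columns were -0.09, 0.03, -0.15 and 0.05 for replicates 1, 2, 4 and 5, so the table was not centred on the median of the probes. The table held 0 further value columns.

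The signals of all spots were background-corrected with normexp (offset 50), and log2 ratios were normalized by loess within each array, with control spots at weight 0. Spots with an outlier mark were left out (26 to 38 per array), no spot was saturated, and spots of a probe were averaged. Every ratio was then turned to knockout over wild type by the dyes in the labels. Of 43603 probes, 29606 were kept because their signal was well above background in the knockout channel of at least 3 arrays or in the wild-type channel of at least 3. Probes were named through the table of RefSeq genes of assembly WBcel235, used for names only: 34922 by sequence name, 332 by transcript accession and 1456 by the gene name in the file, while 6893 had no match and kept the file's name. A total of 1605 probes name more than 1 gene in the file. Each gene was represented by its probe with the highest mean intensity, which left 16670 genes, 15312 of them matched. Among 5011 genes with several kept probes, 3 had a probe that differed from the chosen one by more than 1 on the log2 scale. Probe positions are those of the array design, on genome build ce4.

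The share of probes well above background stands in for depth. It was 72.4, 67.6, 64.9 and 68.2% in the knockout channel and 69.5, 69.0, 62.7 and 69.1% in the wild-type channel of replicates 1, 2, 4 and 5. The number of arrays limits the precision.

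The comparison was made with limma 3.58.1 in R 4.3.3, with the turned log2 ratio as the response, a term for the dye orientation, empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05, two-sided. pdf-1 also had an exact two-sided permutation of signs over the arrays. The 35 gene lists, and the rule for the genes named, were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, each adjusted over the 35 lists. The rule names pdf-1, up to 12 called genes in each direction that moved the same way on all 4 arrays, the 10 genes with the smallest p in each direction where fewer than 20 genes are called (as values only), and up to 4 members with the smallest p of each list described. A test of the chromosomes of called genes was planned and could not be run, since no gene was called.

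The alternatives, chosen before the data were examined, were the processed signals centred on the median, no background correction, Aquantile between arrays, median centring in place of loess, the authors' value table, no filter on dim probes, a filter requiring all 8 channels, no dye term, the 8 channels taken as single samples after quantile normalization, the mean of all probes of a gene, trended and robust moderation, array weights, each array left out in turn, other thresholds and the estimated correlation. A stage score (the mean ratio of the oocyte list on each array) in place of the dye term, a fit of replicates 4 and 5 alone, the channels as single samples without quantile normalization, and quantile normalization with the pairing kept were added after seeing the data. The channels taken as single samples after quantile normalization, which change the pairing and the normalization together, are called no replicate block below. With an array left out, the dye term leaves another alone in its orientation. That array is fitted exactly and weighs as much as the remaining arrays together.

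The fit was tested on simulated data for the comparison of knockout with wild type, with 16657 genes, 200 of them changed. The spread of each gene was the root mean square of its ratios about 0, scaled by the spread of each array. This counts a gene's own mean difference as spread, and genes were drawn independently, so recovery at the real spread was not measured. Of the genes changed 8-fold, 54% were recovered, of those changed 4-fold 26%, and of those changed 2-fold or 1.5-fold 0%, with 0 unchanged genes called. With that spread multiplied by 0.1, 100, 100, 98 and 90% were recovered at 8, 4, 2 and 1.5-fold, with 2 unchanged genes called. Figures were drawn with matplotlib from the same tables.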

Results

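The series measured messenger RNA in whole young adult hermaphrodites of C. elegans that lack pdf-1, a gene encoding neuropeptides of the pigment dispersing factor family, which act on neurons and muscle. The question, from the title of the series, was what loss of the gene does to expression. Each of 4 arrays set 1 knockout RNA against 1 wild-type RNA, so every value below is a log2 ratio of knockout over wild type within an array, with n = 4 arrays.

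pdf-1 itself was lower in the knockout on all 4 arrays. Its single probe (sequence name T07E3.6, chromosome III, 6910026 to 6910085, ce4) gave log2 ratios of -2.86, -2.61, -2.94 and -3.14 on replicates 1, 2, 4 and 5. The mean was -2.89 ± 0.22 (SD, n = 4), a 7.41-fold lower signal, and the fold lay between 6.11 and 8.84 on the single arrays. The difference was far larger than the spread between arrays, and in the exact two-sided permutation of signs 2 of 16 arrangements were as extreme, the smallest share that 4 arrays allow. In limma across all genes its adjusted p was 0.741, past no threshold. The knockout signal of this probe remained well above background on 4 of 4 arrays. The labels do not give the deleted part of the gene, so it is unknown whether the probe lies within it.

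Apart from pdf-1, the arrays disagreed about which genes were higher in the knockout, above all for genes of the adult germ line and yolk. The SD of the log2 ratio over genes was 0.37, 1.17, 0.47 and 0.21 on replicates 1, 2, 4 and 5, and 448, 3018, 835 and 40 genes lay 2-fold or more apart. Replicate 1 ran against the others. Across genes, which are not independent replicates, its log2 ratios correlated with those of replicates 2, 4 and 5 at r = -0.40, -0.57 and -0.25, while the other 3 pairs of arrays had r = 0.45, 0.40 and 0.39. Over all probes, replicates 1 and 4, which share a dye orientation, had r = -0.53. The dyes in the labels and the low pdf-1 signal on all 4 arrays settle the direction, so no array was turned. On replicate 2 the yolk protein gene vit-2 had a log2 ratio of -5.24 and the adult cuticle collagen gene col-19 one of -6.16, against 2.06 and 1.28 on replicate 1.

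**Figure D1:**
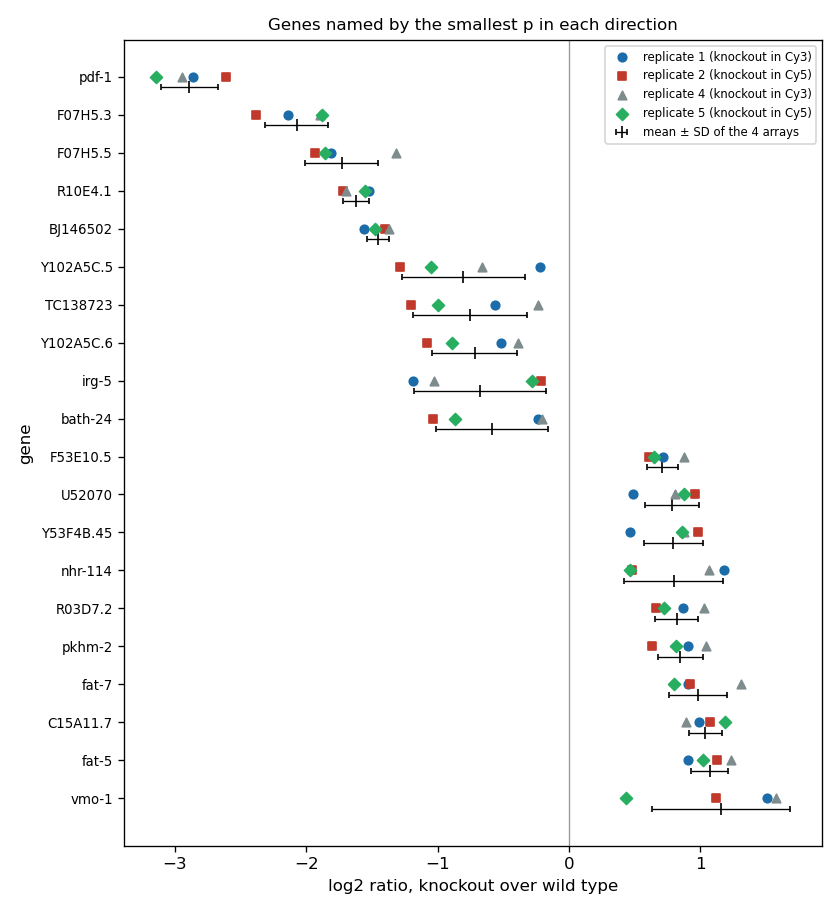
Log2 ratio of knockout over wild type on each of the 4 arrays (symbols, horizontal axis) for the genes named by the smallest p in each direction (vertical axis). Black bars give the mean ± SD of the 4 arrays. pdf-1 lies furthest to the left, with a mean of -2.89, and all 20 genes lie on 1 side of 0 on all 4 arrays.

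Over the whole transcriptome, no gene passed the threshold. With limma, 0 of 16670 genes had an adjusted p under 0.05, while 257 had an unadjusted p under 0.05, 205 of them higher and 52 lower in the knockout. The 257 are fewer than the share of 0.05 that genes without any difference would give, so they are no excess. With the signs of replicates 2 and 4 turned, 386 genes had an unadjusted p under 0.05 in limma, and with those of replicates 4 and 5 turned, 326. A total of 2035 genes had the same sign on all 4 arrays, where independent arrays with random signs would give 2084. The arrays were correlated over genes, with replicate 1 against the others, so the 2 counts do not measure agreement against chance. Without replicate 5, the fit called 949 genes, 943 of them lower. There replicate 2 was alone in its dye orientation and was fitted exactly. With the 8 channels taken as single samples after quantile normalization, 2 genes were called, F07H5.3 and pdf-1. With the pairing alone removed it was 1, pdf-1, and with quantile normalization alone 0.

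The genes with the smallest p are given as values, not as changes, and each had an adjusted p of 0.741 in limma. On the lower side, next to pdf-1, stood F07H5.3 at -2.07 ± 0.24 (SD, n = 4), F07H5.5 at -1.73 ± 0.28 and R10E4.1 at -1.62 ± 0.10. An expressed sequence tag, BJ146502, whose probe lies on chromosome II at 8788889 to 8788948, was at -1.45 ± 0.08. This position lies between probes of F07H5.5, 1 of them ending at 8788426 and another starting at 8789508, so the tag may be part of the same gene and not a separate one. Y102A5C.5 was at -0.81 ± 0.47 and its neighbour on chromosome V, Y102A5C.6, at -0.72 ± 0.32. The unmatched cluster TC138723, whose probe starts at 16929816 on chromosome V, close to that of Y102A5C.6, was at -0.75 ± 0.43. irg-5, an infection response gene, was at -0.68 ± 0.50 and bath-24 at -0.59 ± 0.43.

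On the higher side, vmo-1 was at 1.16 ± 0.53 (SD, n = 4), fat-5 at 1.07 ± 0.14, C15A11.7 at 1.04 ± 0.13 and fat-7 at 0.99 ± 0.22. fat-5 and fat-7 encode delta-9 fatty acid desaturases, which make monounsaturated from saturated fatty acids. pkhm-2 was at 0.85 ± 0.17, R03D7.2 at 0.82 ± 0.16, the nuclear hormone receptor gene nhr-114 at 0.80 ± 0.38 and F53E10.5 at 0.71 ± 0.12. Y53F4B.45 was at 0.80 ± 0.23, and U52070, a sequence whose probe lies beside it on chromosome II (from 15043811, against 15042700), at 0.78 ± 0.20. For these genes the differences exceeded the spread between the 4 arrays, but not the adjustment over 16670 genes.

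Gene groups fixed before the data were examined were compared with all other genes by limma's camera. At the preset correlation, 18 of 35 lists passed an adjusted p of 0.05, 14 higher and 4 lower in the knockout. With an estimated correlation 0 lists passed, and each of the 18 had an adjusted p = 0.799 there. With limma's fry 0 lists passed as well, the smallest adjusted p being 0.803. The estimated correlation ran from -0.029 for the male neuron markers to 0.999 for the major sperm proteins, and was 0.34 for the lysozymes. With an estimated correlation, camera also used the 2 residual degrees of freedom of the fit, which left any list little room to pass. For the UDP-glucuronosyltransferases the estimated correlation was -0.012, below the preset 0.01, yet the unadjusted p in camera rose from 0.00587 to 0.0731. The lost calls therefore cannot be laid to correlation alone. Below, camera results under the alternatives for processing use the preset correlation, which takes members that move together as nearly independent. In all 35 lists 0 members passed when adjusted over all genes tested. Counts adjusted over the list alone were 2 for the fatty acid list and 0 for every other list.

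Genes of fatty acid synthesis, desaturation and elongation stood higher in the knockout on all 4 arrays. Their median log2 ratios were 0.49, 0.08, 0.26 and 0.41 on replicates 1, 2, 4 and 5, and the median of the fitted values was 0.31 over 20 measured members. Camera gave an adjusted p = 6.57e-08 at the preset correlation, and an adjusted p = 0.799 with an estimated correlation. Of the 20 members, 16 were higher and 4 lower on average, and 9 were higher on all 4 arrays. fat-5 and fat-7 were the 2 that passed when adjusted over the list alone, with an adjusted p of 0.0185 each in limma. fat-6, also a delta-9 desaturase gene, was at 0.56 ± 0.12 (SD, n = 4), and fat-3, the delta-6 desaturase of polyunsaturated fatty acid synthesis, at 0.66 ± 0.24, both short of the threshold within the list. fat-6 and fat-7 are close paralogs, and their signals are uncertain to the extent that a probe binds both transcripts. Intestinal markers, a separate list with no shared member, had medians of 0.25, -0.34, 0.05 and 0.35 on replicates 1, 2, 4 and 5, so both lists were lowest on replicate 2 and high on replicates 1 and 5. The elongase gene elo-7 lay lowest, at -0.80 ± 1.62, with -3.22 on replicate 2.

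**Figure D2:**
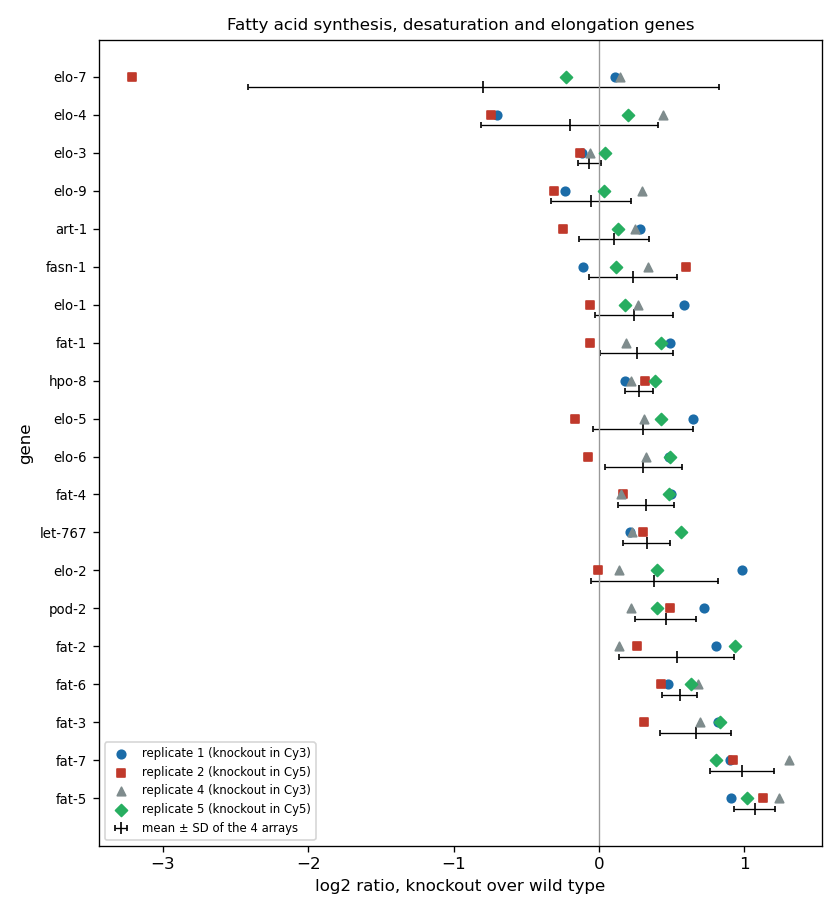
Log2 ratio of knockout over wild type on each array (symbols, horizontal axis) for the 20 measured genes of fatty acid synthesis, desaturation and elongation (vertical axis). Black bars give the mean ± SD of the 4 arrays. fat-5 and fat-7, with means of 1.07 and 0.99, lie above 0.8 on all arrays, while elo-7 falls apart from the rest on replicate 2 at -3.22.

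Other lipid genes gave no call in the main fit. Among 42 genes of beta-oxidation, the breakdown of fatty acids, 27 were higher and 15 lower, with a median of 0.05 and an adjusted p = 0.0832 in camera. hacd-1 was at 0.64 ± 0.24 (SD, n = 4), ech-7 at 0.41 ± 0.29 and the acyl-CoA synthetase gene acs-2 at 0.74 ± 0.38, higher on all 4 arrays. The beta-oxidation list was called without replicate 1 (median 0.18, adjusted p = 0.0188 in camera) and without replicate 2 (0.097, 0.00351), while without replicate 4 its median was -0.042. It was also called with median centring (median 0.25, 0.00973), quantile normalization with the pairing kept (0.13, 0.0383) and replicates 4 and 5 alone (0.18, 0.00724). Lipases and lipid-binding proteins had 10 members higher and 10 lower (adjusted p = 0.706 in camera) and were called without replicate 2 (0.0490). The 6 vitellogenin genes, which encode yolk proteins, had medians of 2.03, -4.88, -1.34 and 0.25 on replicates 1, 2, 4 and 5 and were not called (adjusted p = 0.142 in camera). They were called lower with the processed signals (0.0378), median centring (0.00973), the authors' value table (0.0466) and no replicate block (0.0267), as well as without replicate 5 (median -2.20, 0.00574), and without replicate 2 the median was 0.35.

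Neuropeptide genes lay higher on 3 of 4 arrays. Of 29 FMRFamide-like peptide genes, 28 had a fitted ratio above 0, with a median of 0.26. Of 60 neuropeptide-like protein genes it was 56, with a median of 0.17. Camera gave adjusted p = 6.57e-08 and 2.87e-08 for these lists at the preset correlation and 0.799 for both with an estimated correlation. On replicate 1 both medians lay below 0, at -0.13 and -0.09, and the fitted medians ran from 0.097 and 0.081 without replicate 4 to 0.41 and 0.27 without replicate 1. flp-1 was at 0.47 ± 0.33 (SD, n = 4), flp-14 at 0.37 ± 0.25, nlp-21 at 0.41 ± 0.33 and pdf-2, which encodes the second PDF peptide and lies in the list of neuropeptide-like proteins too, at 0.44 ± 0.42. In the list of PDF signalling genes (8 members, median 0.16, adjusted p = 0.0338 in camera, 0.799 with an estimated correlation), the receptor gene pdfr-1 was at 0.20 ± 0.19 and the adenylate cyclase gene acy-1 at 0.25 ± 0.18. The PDF signalling list was no longer called without replicate 1, 2 or 4 (median 0.23, 0.072 and 0.10, adjusted p = 0.101, 0.398 and 0.126 in camera).

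Other neuronal lists lay in the same direction. Pan-neuronal markers (14 members, median 0.26, adjusted p = 0.000973 in camera), neuropeptide processing genes (13, 0.28, 0.00286), classical neurotransmission genes (18, 0.12, 0.0338) and insulin-like peptides (31, 0.10, 0.0338) passed at the preset correlation, each with an adjusted p = 0.799 with an estimated one. Among the markers rab-3 was at 0.37 ± 0.44 (SD, n = 4) and unc-64 at 0.29 ± 0.31, among the processing genes pgal-1 was at 0.37 ± 0.26, and the insulin-like gene ins-35 was at 1.25 ± 0.75. Clock gene homologs (5, 0.20, adjusted p = 0.130 in camera), male neuron markers (4, 0.07, 0.336) and chemoreceptors (110, 0.01, 0.646) were not called. Without replicate 4 the processing list was not called (median 0.15, adjusted p = 0.0570) and the median of the pan-neuronal markers was 0.12; without replicate 2 the medians of the 2 lists were 0.18 and 0.16. Neither the neurotransmission list (adjusted p = 0.120, 0.581 and 0.126) nor the insulin-like list (0.0595, 0.304 and 0.163) was called without replicate 1, 2 or 4. In the fit of replicates 4 and 5 alone, chosen after seeing the data, these lists and PDF signalling were not called (adjusted p = 0.408, 0.0839 and 0.240 in camera). The other neuronal lists called in the main fit were still called there. The neurotransmission call was also lost with the processed signals (0.0621), median centring (0.0772) and no replicate block (0.118), and the insulin-like call with no background correction (0.0810) and median centring (0.131). With the mean ratio of the oocyte list as a covariate, an alternative chosen after seeing the data, the neurotransmission, insulin-like and PDF signalling lists were not called (adjusted p = 0.0842, 0.271 and 0.117 in camera), and the medians of the FMRFamide-like peptides, neuropeptide-like proteins, processing genes and pan-neuronal markers, still called, were 0.13, 0.090, 0.18 and 0.13. The neuronal lists lay higher on replicates 2, 4 and 5. The germ line lists lay lower on replicates 2 and 4. On replicate 5 the oocyte (-0.29), other sperm (-0.10) and mitotic and meiotic (-0.18) medians lay below 0 too, and that of the major sperm proteins was 0.06. The pan-neuronal medians were -0.12, 0.69, 0.28 and 0.17 on replicates 1, 2, 4 and 5. They ran in the reverse order of the oocyte medians, 1.19, -2.74, -0.69 and -0.29.

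Germ line lists stood lower in the knockout on average, with the largest values on replicate 2. Major sperm protein genes (27 members, all 27 with a fitted ratio below 0) had medians of 1.12, -5.43, -0.93 and 0.06 on replicates 1, 2, 4 and 5. Oocyte and eggshell genes (24 of 24 below 0) had medians of 1.19, -2.74, -0.69 and -0.29, other sperm genes (49 of 49) 0.27, -2.96, -0.32 and -0.10, and mitotic and meiotic germ line genes (19 of 19) 0.29, -0.95, -0.38 and -0.18. Camera gave adjusted p = 9.23e-06, 7.02e-05, 5.26e-10 and 3.69e-06 at the preset correlation, and 0.799 for each of the 4 lists with an estimated correlation. cey-2 was at -0.68 ± 1.47 (SD, n = 4), oma-1 at -0.56 ± 1.36 and msp-142 at -1.26 ± 2.59, so the spread between arrays exceeded the mean. Without replicate 2 the fitted median of the major sperm proteins was 0.08 (adjusted p = 0.838 in camera) and that of the oocyte list -0.01 (0.273), while without replicate 5 they were -2.66 and -1.25. Without replicate 2, replicate 5 weighed as much as replicates 1 and 4 together, and without replicate 5, replicate 2 did. Without replicate 4 the oocyte list was not called either (0.476). The other sperm and the germ line lists were still called without replicate 2, at medians of -0.053 and -0.15, and the latter was at -0.16 without replicate 4. On replicates 4 and 5 alone, a fit chosen after seeing the data, all 4 lists were called lower, the major sperm proteins at -0.44, other sperm genes at -0.21, the oocyte list at -0.50 and the mitotic and meiotic list at -0.31. With the stage score, which is made from it, the oocyte list was not called (0.834). The major sperm proteins, other sperm genes and mitotic and meiotic genes were still called lower there. cey-2, oma-1 and msp-142 were then at -0.094, -0.023 and -0.26. The major sperm proteins are near-identical copies, and 8 of their 27 probes name more than 1 gene in the file. Early zygotic embryonic genes (16, -0.03, adjusted p = 0.611 in camera) were not called.

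**Figure D3:**
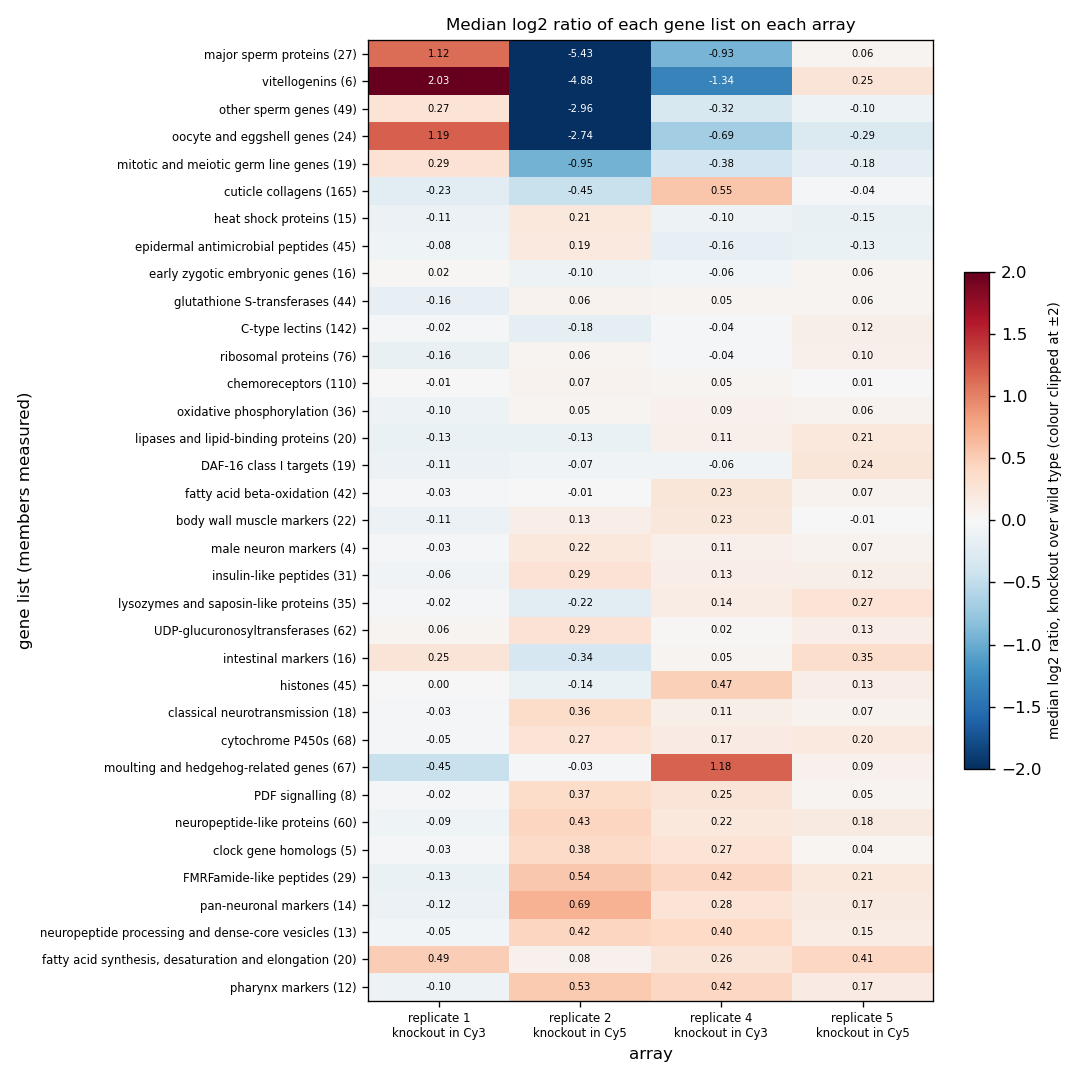
Median log2 ratio of knockout over wild type of each gene list (vertical axis, number of measured members in parentheses) on each array (horizontal axis), with the value printed in each cell and the colour clipped at ±2. The vitellogenin, sperm and oocyte lists run from 2.03 on replicate 1 to -5.43 on replicate 2, while the fatty acid list lies above 0 on all 4 arrays.

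Cuticle and moulting genes also differed between arrays. Moulting and hedgehog-related genes, which rise around each larval moult, had medians of -0.45, -0.03, 1.18 and 0.09 on replicates 1, 2, 4 and 5 over 67 members. Their adjusted p was 0.0329 in camera, and 0.799 with an estimated correlation. Without replicate 4 the median was -0.13, and camera called the list lower, the opposite direction (adjusted p = 0.000422). The call was lost with the processed signals (adjusted p = 0.0966 in camera), no filter on dim probes (0.0511), a filter on all 8 channels (0.0969), no replicate block (0.146) and the stage score (median 0.070, 0.217). Neither removing the pairing alone nor quantile normalization alone lost it. grd-10 was at 0.80 ± 0.70 (SD, n = 4) and wrt-10 at 1.14 ± 1.14. Cuticle collagens (165 members, 62 higher and 103 lower, median -0.10) were not called (adjusted p = 0.164 in camera). Without replicate 4 they were called, with a median of -0.29 (adjusted p = 4.77e-06 in camera), and without replicate 1 or 2 the median was 0.090 or 0.020. They were also called with the processed signals (median -0.040, 0.0230) and no replicate block (-0.021, 0.0207). col-105 was at -0.36 ± 0.16.

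Detoxification and immune genes gave 2 calls. Cytochrome P450 genes (68 members, 45 higher, median 0.13, adjusted p = 0.000973 in camera) and UDP-glucuronosyltransferase genes (62, 40 higher, 0.10, 0.0158) passed at the preset correlation, with an adjusted p = 0.799 for both with an estimated correlation. cyp-34A10 was at 0.83 ± 0.34 (SD, n = 4) and ugt-18 at 0.39 ± 0.17, higher on all 4 arrays. Without replicate 1 the UDP-glucuronosyltransferases were not called (adjusted p = 0.433 in camera), nor on replicates 4 and 5 alone (0.121), nor with no replicate block (0.0547). With the pairing alone removed (0.0228) or quantile normalization alone (0.0239) they were still called. The cytochrome P450 median lay between 0.079 without replicate 4 and 0.21 without replicate 1, called in both. Glutathione S-transferases (44, -0.03, adjusted p = 0.757), C-type lectins (142, -0.02, 0.757), lysozymes and saposin-like proteins (35, 0.10, 0.0850), epidermal antimicrobial peptides (45, -0.04, 0.142), DAF-16 class I targets (19, 0.05, 0.552) and heat shock proteins (15, -0.07, 0.492) were not called by camera. Without replicate 2, camera called the lysozymes (median 0.14, adjusted p = 7.77e-08), the epidermal peptides (-0.10, 5.97e-06), the C-type lectins (0.044, 0.00127) and the heat shock proteins (-0.095, 0.000116), and without replicate 1 the epidermal peptides (-0.14, 0.0166). It also called the lysozymes with median centring (0.0388), no replicate block (0.0492) and quantile normalization with the pairing kept (0.0308), but not with the pairing alone removed (0.333). The epidermal peptides were called with the processed signals (0.0168), median centring (0.0205) and the authors' value table (0.0245). gst-24 was at 1.06 ± 0.61 and clec-3 at 0.71 ± 0.29, higher on all 4 arrays. For the C-type lectins the median lay below 0 and the test pointed up, and for the glutathione S-transferases the mean (0.01) lay above 0 and the test pointed down.

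Of the tissue and housekeeping lists, pharynx markers (12 members, median 0.32, adjusted p = 0.00771 in camera), histones (45, 0.12, 0.00879) and intestinal markers (16, 0.11, 0.0383) stood higher at the preset correlation, each with an adjusted p = 0.799 with an estimated one. pha-4, a regulator of pharynx identity, was at 0.61 ± 0.45 (SD, n = 4), the intestinal cathepsin gene cpr-5 at 0.39 ± 0.16 and his-24 at 0.62 ± 0.61. For the histones 20 of 45 probes name more than 1 gene. With an array left out, camera no longer called the pharynx list without replicate 4 (median 0.19, adjusted p = 0.484), the histones without replicate 4 or 5 (medians -0.0083 and 0.072, adjusted p = 0.674 and 0.239) and the intestinal markers without replicate 1 or 5 (medians 0.034 and -0.053, adjusted p = 0.533 and 0.744). The intestinal call was also lost with the processed signals (0.0621) and in the authors' value table (0.0738). Without replicate 2 the intestinal median was 0.27 and that of the histones 0.18, and without replicate 1 that of the histones was 0.25. Body wall muscle markers (22, 0.07, 0.184), ribosomal proteins (76, 0.00, 0.903) and genes of oxidative phosphorylation (36, 0.02, 0.706) were not called by camera. Median centring called all of these 3 lists higher (adjusted p = 0.00402, 0.000117 and 0.0157), and it also moved the median of all genes up to 0.13. With no replicate block, which also changed the normalization, the muscle markers (0.0365) and ribosomal proteins (0.00118) were called higher. Quantile normalization with the pairing kept called the ribosomal proteins higher too. For the ribosomal protein, oxidative phosphorylation and chemoreceptor lists the median, mean and test differed in sign, all near 0.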

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

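Of the tests in this part, only the splits that gave counts of called genes and lists, and the comparison of spike-in transcripts on replicate 2 with all other arrays, were chosen before their results were seen. The 2 patterns weighed below were noticed in these data first. For the first of them, an exchange of the RNAs on replicate 1 and dye bias were examined in an earlier run and are left out here.

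A total of 13 of 194 values examined had 1 array far from the other 3, where independent, normally distributed values would give about 9.7. On replicate 2 these were the log2 ratios of cyc-2.2 (-3.84), spe-10 (-2.92), mtl-2 (-1.66), spe-38 (-1.65), lipl-3 (-0.17), hsp-16.1 (0.52), cyp-13A12 (0.73) and cyp-13A11 (0.77), and the median of the heat shock proteins (0.21). On replicate 1 they were ins-29 (-0.036) and the median of the glutathione S-transferases (-0.16), on replicate 5 the median of the DAF-16 class I targets (0.24), and on replicate 4 the share of probes well above background in the wild-type channel, 62.7%. Many of the values were genes picked for a small p, and the probes of cyp-13A11 and cyp-13A12 each name the other gene. The count of 13 therefore does not measure an excess over chance.

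Genes of the germ line, yolk and adult cuticle differed between the arrays. An effect of the knockout common to all pairs, as the only source, would give 1 sign, but the oocyte and eggshell list had a median log2 ratio of 1.19 on replicate 1 and -2.74 on replicate 2. A fault of labelling or hybridisation on replicate 2 would also move the spike-in transcripts. Their log2 ratio of red over green differed there from the mean of the other arrays by a median of 0.14, under the bound of 0.2 set beforehand for excluding it. Replicate 1 was itself 0.56 from the rest, and from replicates 4 and 5 alone the difference was 0.22 (largest 0.36), past that bound. A small fault was therefore not decided. The largest spike-in difference, 0.36, was far below the size of the oocyte median of -2.74 on replicate 2. The spike-in values thus argue against such a fault as the source of differences of that size. A difference in developmental stage between paired cultures was not decided: on replicates 1, 2 and 4 the vitellogenin, major sperm protein and oocyte medians and the adult collagen genes col-19 and col-129 shared 1 sign, but on replicate 5 the medians of vitellogenins (0.25) and major sperm proteins (0.06) lay against that of the oocyte list (-0.29), col-19 (-0.52) and col-129 (-0.17), and these genes had been seen before the test was written. As a hypothesis, the knockout animals may have been older than their wild-type partners on replicate 1 and younger on replicates 2 and 4, which scoring the stage of paired cultures before RNA extraction would test.

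The list of fatty acid synthesis, desaturation and elongation genes had medians above 0 on arrays whose germ line genes went opposite ways, with an adjusted p = 0.799 in camera with an estimated correlation. The median of its 20 measured members was fitted on the 4 arrays against a stage score, the mean ratio of the oocyte list on each. It was 0.38 at a score of 0 (standard error 0.03, 2 residual degrees of freedom). The pattern is itself medians above 0 on all 4 arrays, and the scores ran from -2.92 on replicate 2 to 1.19 on replicate 1. A fitted value above 0 was thus largely set in advance, so a trend that follows the oocyte genes was not decided as a source. Dye bias would turn the sign with the orientation, and the lowest array median was 0.081. That value restates the pattern, so it is no separate test of dye bias. A strain difference other than pdf-1 stays open and cannot be told apart from an effect of pdf-1 with 1 knockout strain, and a larger share of intestinal RNA was not tested. As a hypothesis, loss of pdf-1 may raise delta-9 desaturase transcripts, which a second allele or a rescued strain would test.

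Other ways of turning the arrays show how far the counts depend on their grouping. Turning the sign of single arrays gives 7 splits that can be fitted with the dye term, too few for a share under 0.05. The real one called 0 genes, so all 7 gave as many, and the highest other called 1567, with replicate 5 turned. With a single array turned, another array was alone in its dye orientation, unlike in the real split, and was fitted exactly. With replicate 5 turned this was replicate 2, so the 1567 is no measure of chance. For gene lists, 2 of the 7 splits called as many as the real 18, and the highest other called 18.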

How the results depend on the processing

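The stage score covariate, the fit of replicates 4 and 5 alone, and the fits that changed the pairing or the quantile normalization alone were chosen after seeing the data. The count of 0 called genes, by limma, was the same under most alternatives. With no replicate block, where the 8 channels were single samples after quantile normalization, it was 2; with the pairing alone removed it was 1 and with quantile normalization alone 0. With arrays left out it ranged from 0 to 949, the highest without replicate 5, where 943 of the called genes were lower. In that fit replicate 2 was alone in its dye orientation, so it was fitted exactly and the residual spread came from replicates 1 and 4. How much of the count this explains was not tested. Unadjusted p under 0.05 were given by 98 to 2500 genes with an array left out. pdf-1 kept its direction under all 20 alternatives, from -3.29 to -2.71, and its adjusted p ranged from 0.0119 to 1.00; it passed the threshold at -2.88 with no replicate block, at -2.89 with the pairing alone removed and at -2.76 without replicate 5, and with arrays left out its value lay between -3.02 and -2.76. Each of the other 19 genes named by smallest p also kept its sign under 20 of 20 alternatives. These genes lay on 1 side of 0 on all 4 arrays, so leaving arrays out could not turn their sign. Over all named genes, those of the lists included, 3110 results stayed on their side of the threshold and 14 passed it, each in the direction of the main value. With 0 genes called in the main fit, no call could be lost. The count of 18 called lists became 0 with an estimated correlation, and otherwise lay between 12 and 24. Over lists and alternatives, 580 results stayed on their side of the threshold, 41 calls were lost, 38 were gained, and in 6 the direction that camera gave was turned with a call before or after. The last were the chemoreceptors (median -0.021) and ribosomal proteins (0.27, where the main median was 0.00 and camera pointed down) with median centring in place of loess, the ribosomal proteins with no replicate block and with quantile normalization alone (0.10 in both), the moulting genes without replicate 4 (-0.13, the lowest with an array left out, against a highest of 0.63 without replicate 1) and the major sperm proteins without replicate 2 (0.075, the highest, against a lowest of -2.66 without replicate 5). The median itself changed sign in 56 results over 19 lists, 10 of them with a call before or after. Median centring also moved the median of all genes to 0.13, from -0.005. The fatty acid list passed camera at the preset correlation under every alternative run. Aquantile leaves the ratios as they are, and array weights lay near 1, so neither could change a result. Trended moderation was not run for lists, and the chromosomes of called genes were not run. Between 62.7 and 72.4% of probes were well above background in a channel. Probes that failed the filter on dim signal were left out of the main fit. With no such filter 23562 genes were tested.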

Other observations

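All tests and counts in this part were chosen after seeing the data.

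A small set of genes stood apart in 1 direction on all 4 arrays whatever the state of the germ line genes. A total of 14 genes, counting BJ146502, which may be part of F07H5.5, were 1.5-fold or more apart on every array, 5 lower and 9 higher in the knockout, and 6 were 2-fold or more apart on every array. Besides pdf-1, F07H5.3, F07H5.5, R10E4.1, BJ146502, F53E10.5, R03D7.2, pkhm-2, fat-7, C15A11.7 and fat-5, they were tts-1, a long noncoding RNA, at 1.61 ± 0.53 (SD, n = 4), F19B10.1 at 1.09 ± 0.31 and T20F7.1 at 0.91 ± 0.32. Of the 8 ways of turning the arrays only 1, the real one, gave as many, and the highest other gave 13, with replicate 1 turned against the rest, and 0 genes at 2-fold. With BJ146502 and F07H5.5 taken as 1 gene the real count would be 13 too, so that the lead at 1.5-fold depends on this choice. With 8 splits no share under 0.05 can be reached. The count was 43 with the processed signals, 31 with median centring and 39 in the authors' value table.

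Genes lower in the knockout at an unadjusted p under 0.05 tended to be neighbours. Among 45 such genes, 6 pairs were next to each other in the order of 14616 genes on the chromosomes, against 0.13 in random sets of the same size, so chance position is an unlikely source (permutation p = 0.0001, the smallest 10000 draws can give). The genes were F07H5.3, F07H5.4 and F07H5.5 on chromosome II, Y102A5C.36, Y102A5C.5 and Y102A5C.6 and the pair srd-63 and F13A7.11 on chromosome V, and clec-67 and clec-69 on chromosome IV. Among 175 higher genes there were 8 pairs against 2.07 in random sets (permutation p = 0.0011), so neighbours that move together are not special to the lower genes. The test was first run at an unadjusted p under 0.01, and the limit of 0.05 was taken after that result was seen. At 0.01, 9 lower genes held 1 pair against 0.0051 in random sets (permutation p = 0.0052), and 20 higher genes held 0 pairs. Deletion of the genes in the knockout strain was not decided. The median knockout log2 signal of the 10 genes was 10.02 (from 7.16 for Y102A5C.36 to 15.35 for F07H5.5), while 99% of 11301 dim probes, not well above background in any knockout channel, lay below 7.27, but pdf-1 itself, at 8.77, lay above that level too. Of the 10 genes 8 lay above the level of the dim probes and 7 above the signal of pdf-1, and the differences of the 10 were 1.26 to 4.21-fold. Signals of different probes are not on a common scale, and it is unknown whether the pdf-1 probe lies within the deleted part. These counts therefore do not decide on a deletion. A strain difference other than pdf-1 may be behind them, and with 1 knockout strain it cannot be told apart from an effect of pdf-1.

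The spike-in transcripts gave log2 ratios of red over green from -2.88 to 3.06 on replicate 2, and their SD over the 10 transcripts was 1.85, 1.86, 1.84 and 1.86 on replicates 1, 2, 4 and 5. On replicate 1 they differed from the mean of the other arrays by a median of 0.56.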
